A study of Mus musculus with 24 samples.

How the data were processed

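Gene expression was measured in the cerebral cortex and hippocampus of male C57BL/6J mice with Affymetrix oligonucleotide arrays. The 24 arrays fell into 8 groups of 3, one for each combination of region, genotype (wild type, WT, or ApoD knockout, KO) and age (100 or 655 days). Per the labels' protocols, each array received a pool of equal amounts of total RNA from 2 to 3 mice drawn at random, and the 3 pools of a group are called biological replicates. A p-value therefore reflects the spread between pools of mice, which is smaller than that between single mice. The labels do not say whether cortex and hippocampus pools came from the same mice, and they give no hybridization batch.

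The deposited table holds log2 signal values of 23879 Ensembl gene IDs on 24 arrays, from 3.99 to 14.4, with 0 missing values. Per the submitters' processing notes, MAS5 and RMA were used, with no role or version given for either. The array model, the annotation build and the rule that joined probes into gene IDs are not given in the sources used here. The log2 unit was inferred from the range of the values and the similar medians of the arrays, 7.31 to 7.42. Detection calls, control probe sets and scanner files were not used here, so the level below which a signal is background is unknown, and the folds of dim IDs are uncertain. The number of arrays limits the precision, and array values carry no read depth.

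The files do not pair the IDs with gene names, and the reference table used here, of assembly GRCm38.p6, matched 0 of the 23879 IDs because it lists 0 Ensembl IDs. Results are therefore given by ID. The rule for named genes, set before the data were examined, took the 10 genes with the largest change in each direction among those past the threshold, with full separation of the 3 arrays of each group in single contrasts. It was reduced to 2 IDs in each direction per comparison, and its parts that need a gene symbol were left out. For the same reason 0 of the 33 planned gene lists, the tests on them, the check of region labels by marker genes and the planned result for Apod by name were run.

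Analysis used R 4.3.3 and limma 3.58.1. IDs whose mean over the 24 arrays lay above the 40th percentile of all IDs (6.63 log2) were tested, which kept 14327 and left out 9552. A model with 8 group means was fitted to all 24 arrays with lmFit, so that each ID had 1 estimate of spread with 16 residual degrees of freedom, and eBayes moderated it. The 15 comparisons were fixed before the data were examined, namely KO minus WT and old minus young within each region, the interactions of age, genotype and region, and KO minus WT averaged over regions and ages. P-values were two-sided and adjusted by Benjamini and Hochberg within each comparison, and an ID was called at an adjusted p under 0.05. "Rose" and "fell" refer to called IDs.

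The procedure was tested on simulated data built from the group means and spreads of the 14327 IDs, with 200 IDs changed. For KO minus WT in young cortex it recovered 28% of the changes of 0.25 log2, 86% of those of 0.5, and 100% of those of 1 and of 2, with 9 unchanged IDs called. For the average of KO minus WT the shares were 94%, 100%, 100% and 100%, with 11 unchanged IDs called. The simulated noise was independent for each ID and array, so no simulated array stood apart from its group. With 200 IDs changed, the adjusted p is also easier to pass than where few IDs change. The shares can therefore overstate the recovery in the real comparisons of KO with WT.

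Age scores were computed after the calls had been seen. For each array, a score was the mean log2 level of IDs that rose with age in both genotypes of the other region, minus the mean of those that fell there. The age changes that chose the IDs came from the other region, but the filter and the spread of each ID came from all 24 arrays, the scored ones included. Scores were compared by two-sided exact permutation tests. With 3 arrays against 3 the smallest p is 0.1.

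The alternatives were no filter on the mean level, a filter at the 60th percentile, quantile normalization, centring of each array on its median, an intensity trend or robust moderation in eBayes, array weights, fits to the arrays of 1 region, the replicate number as a block, a random block for same-numbered pools across regions, and leaving out each array in turn.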

Results

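Messenger RNA levels were measured on 24 arrays of mouse cortex and hippocampus to ask how the loss of apolipoprotein D (ApoD), a secreted lipid-binding protein of the lipocalin family, affects the changes that come with age in each region. Each of 8 groups, formed by region, genotype and age, had 3 arrays, and each array carried a pool of RNA from 2 to 3 mice. Young mice were 100 days old and old mice 655 days old. Array medians lay between 7.31 and 7.42 log2 over 23879 gene IDs, and 14327 IDs were bright enough to be tested. The first principal component of the tested IDs held 67.1% of the variance and separated the 12 cortex arrays from the 12 hippocampus arrays. The next components held 6.46%, 5.07% and 3.97%. Replicate 1 of young KO hippocampus stood apart from the other arrays, with a root mean square deviation of 0.161 log2 from its group mean, where the second highest of the 24 was 0.124.

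The comparison of KO with WT asks which transcripts differ when ApoD is missing. ENSMUSG00000022548 was strongly lower in KO mice of both regions at both ages. No table used here pairs this ID with a gene name, so whether it is the targeted gene is not established. In young cortex its level was 11.71 ± 0.07 log2 in WT and 8.02 ± 0.13 in KO (SD, n = 3 each). In old cortex it was 12.26 ± 0.06 and 8.13 ± 0.10, in young hippocampus 11.78 ± 0.09 and 8.01 ± 0.12, and in old hippocampus 12.49 ± 0.21 and 8.25 ± 0.04. Each of the 12 KO arrays lay below all 12 WT arrays, the highest KO value being 8.29 and the lowest WT value 11.63.

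**Figure D1:**
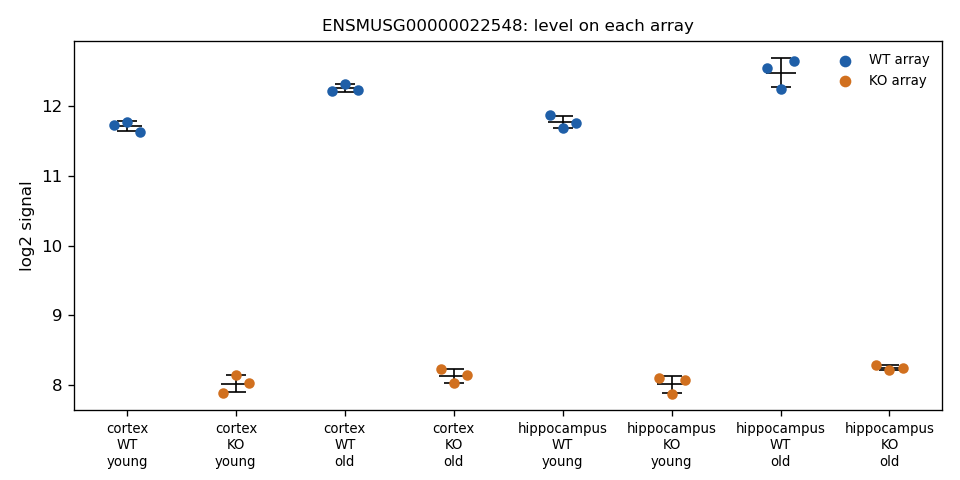
Level of ENSMUSG00000022548 (log2 signal, vertical axis) on each array of the 8 groups. Points are arrays, blue for WT and orange for KO, and black marks are the group mean with SD (n = 3). All KO points lie at or below 8.29 and all WT points at or above 11.63.

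ENSMUSG00000022548 fell by 3.69 log2 (SE 0.088, 12.9-fold) in young cortex, by 4.13 (17.5-fold) in old cortex, by 3.76 (13.6-fold) in young hippocampus and by 4.23 (18.8-fold) in old hippocampus. The limma adjusted p was 1.8e-17, 1.8e-18, 1.2e-17 and 1.0e-18 in that order. It was the 1 ID called in each of these 4 comparisons. IDs with an unadjusted p under 0.05 numbered 411, 847, 940 and 434 of 14327 in the same order, where chance alone gives 716. In young cortex, 9 IDs were called without KO replicate 1, in place of 1, and 2 were called in old cortex without WT replicate 2 or without young KO hippocampus replicate 3, and 2 in old hippocampus without KO replicate 1.

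Averaged over regions and ages, KO differed from WT in 2 IDs, with 12 arrays on each side. ENSMUSG00000022548 fell by 3.95 log2 (SE 0.044, limma adjusted p = 2.4e-24). ENSMUSG00000038094 rose by 0.33 log2 (SE 0.044, 1.26-fold, limma adjusted p = 1.5e-03). Its level was 8.12 ± 0.12 in WT and 8.50 ± 0.04 in KO young cortex, 7.97 ± 0.11 and 8.22 ± 0.14 in old cortex, 8.33 ± 0.07 and 8.77 ± 0.11 in young hippocampus, and 8.63 ± 0.14 and 8.89 ± 0.14 in old hippocampus (SD, n = 3 each). An unadjusted p under 0.05 was found for 819 IDs.

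The comparison of old with young mice describes the change with age. In WT cortex 148 IDs were called, of which 118 rose and 30 fell. ENSMUSG00000082286 rose by 1.20 log2 (SE 0.16, adjusted p = 3.0e-04) and ENSMUSG00000041596 by 1.15 (SE 0.18, adjusted p = 1.6e-03), while ENSMUSG00000009376 fell by 0.83 (SE 0.12, adjusted p = 1.1e-03) and ENSMUSG00000030223 by 0.59 (SE 0.088, adjusted p = 1.1e-03). The count was 84 without young WT replicate 1, 94 without young replicate 2, 77 without old replicate 2 and 70 without old replicate 3.

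In KO cortex 239 IDs were called, of which 161 rose and 78 fell. ENSMUSG00000041596 rose by 1.53 log2 (SE 0.18, adjusted p = 7.3e-05) and ENSMUSG00000082286 by 1.10 (SE 0.16, adjusted p = 6.8e-04), the same 2 IDs that led in WT cortex. ENSMUSG00000062319 fell by 1.21 (SE 0.27, adjusted p = 0.026) and ENSMUSG00000065419 by 1.19 (SE 0.29, adjusted p = 0.038), and these 2 calls were lost under 5 and 8 of the alternative settings. The balance of directions depended on 1 array and on the scaling. Without young KO replicate 3, 154 rose and 158 fell. After quantile normalization 172 rose and 143 fell, and after median centring 179 rose and 153 fell. With array weights 500 were called, and 364 without young KO hippocampus replicate 1, whose spread enters the fit. The count was 112 without young KO replicate 1, 65 without young replicate 2, 122 without old replicate 1, 90 without old replicate 2 and 92 without old replicate 3.

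In WT hippocampus 714 IDs were called, of which 541 rose and 173 fell. ENSMUSG00000073418 rose by 1.33 log2 (SE 0.10, adjusted p = 1.5e-07), from 7.57 ± 0.02 to 8.90 ± 0.02 (SD, n = 3 each), and ENSMUSG00000064365 by 1.19 (SE 0.26, adjusted p = 0.012), a call lost under 3 of the alternative settings. ENSMUSG00000021760 fell by 0.71 (SE 0.096, adjusted p = 3.2e-04) and ENSMUSG00000050822 by 0.59 (SE 0.074, adjusted p = 1.2e-04). The balance of directions depended on the scaling, since after quantile normalization 547 rose and 403 fell, after median centring 383 rose and 528 fell, and with array weights 1445 rose and 774 fell. The count was 396 from hippocampus arrays alone, 177 without young WT replicate 2, 235 without young replicate 3, and 213, 325 and 394 without old replicates 1, 2 and 3.

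In KO hippocampus 771 IDs were called, of which 592 rose and 179 fell. ENSMUSG00000064365 rose by 1.45 log2 (SE 0.26, adjusted p = 2.9e-03) and ENSMUSG00000073418 by 1.30 (SE 0.10, adjusted p = 2.3e-07). ENSMUSG00000072608 fell by 1.35 (SE 0.39, adjusted p = 0.045) and ENSMUSG00000085351 by 0.64 (SE 0.17, adjusted p = 0.029), calls lost under 8 and 5 of the alternative settings. The level of ENSMUSG00000072608 on the 3 young KO arrays ran from 6.81 to 9.24 log2. The balance of directions depended on 1 array and on the scaling. Without young KO replicate 1, the array that stood apart, 239 rose and 281 fell. After median centring 412 rose and 515 fell, after quantile normalization 498 rose and 413 fell, and with array weights 543 rose and 394 fell. The count was 476 from hippocampus arrays alone and 271, 439 and 485 without old KO replicates 1, 2 and 3.

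**Figure D2:**
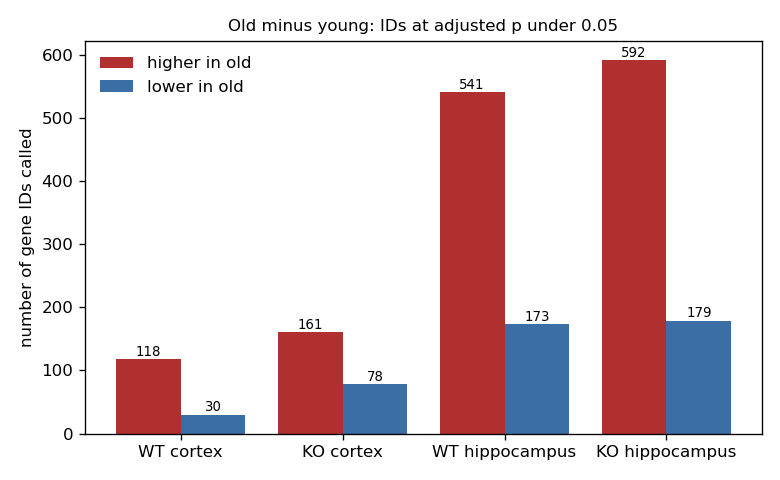
Number of IDs called between old and young mice (vertical axis) in each region and genotype, with red bars for IDs higher in old and blue bars for IDs lower in old mice. In hippocampus 541 (WT) and 592 (KO) were higher and 173 and 179 lower as deposited, and median centring turned this balance to 383 and 412 higher and 528 and 515 lower.

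Of the age calls in cortex, 41 rose and 6 fell in both genotypes, where independent lists would share 1.33 and 0.163. In hippocampus 263 rose and 54 fell in both, against 22.4 and 2.16. No ID was called in opposite directions in the 2 genotypes of a region, a count of 0 in each. Across the 14327 IDs, which are not independent replicates, the WT and KO age changes had r = 0.458 in cortex and 0.648 in hippocampus. No array is shared between these comparisons, but the estimate of spread of each ID is. An ID with a small spread is called more easily in each list. Overlaps above those of independent lists can therefore be partly built in, and this holds for the lists of cortex and hippocampus too. The correlations use the age changes alone and not the spread. Between the regions, 40 rose and 3 fell in both in WT (independent lists 4.46 and 0.362), and 56 and 3 in KO (6.65 and 0.975). In opposite directions in the 2 regions, 3 IDs were called in WT and 0 in KO, and across all tested IDs the age changes of cortex and hippocampus had r = -0.0024 in WT and 0.154 in KO. In all 4 age comparisons 19 IDs rose and 0 fell.

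**Figure D3:**
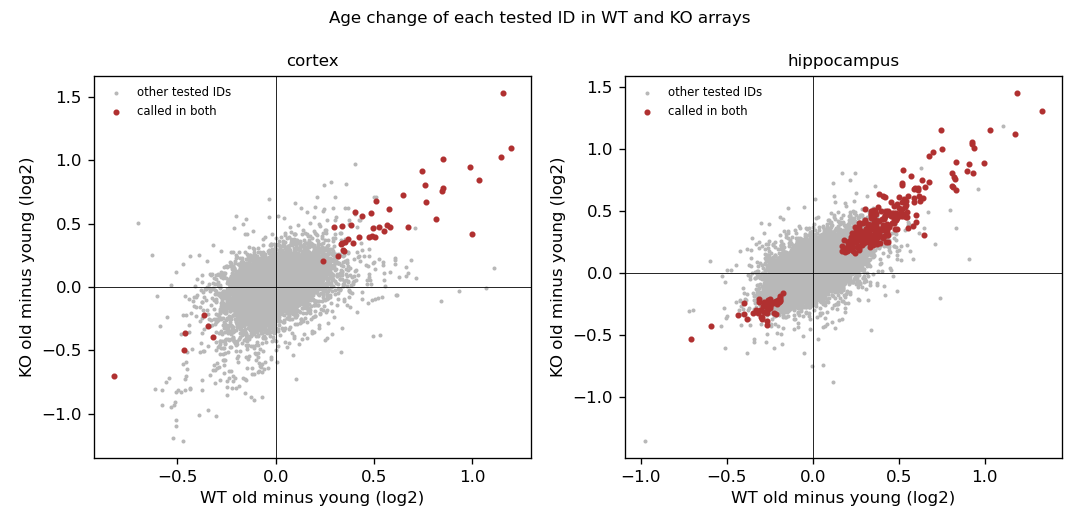
Change with age of each tested ID in WT (horizontal axis, log2 old minus young) and KO mice (vertical axis), with cortex in the left panel and hippocampus in the right. Grey points are tested IDs, and red points the 47 in cortex and 317 in hippocampus that were called in the same direction in both genotypes.

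The interaction of age and genotype asks whether the change with age differs between KO and WT mice. No ID was called, a count of 0 with limma in cortex and 0 in hippocampus. The median SE was 0.1055 log2 in each, and the recovery of such differences was not simulated. The smallest adjusted p was 0.287 and 0.999, and an unadjusted p under 0.05 was found for 889 and 581 IDs, where chance alone gives 716. In cortex 2 IDs were called without young WT cortex replicate 3, and 3 without young KO hippocampus replicate 1. ENSMUSG00000022548 rose with age in WT cortex by 0.55 log2 (adjusted p = 2.0e-03) and in WT hippocampus by 0.71 (adjusted p = 1.2e-04). In KO its change was 0.11 (adjusted p = 0.600) and 0.24 (adjusted p = 0.121), and the difference between genotypes was not past the threshold in cortex (adjusted p = 0.544) or hippocampus (adjusted p = 0.999).

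Whether the effect of ApoD loss on age changes differs between regions, the stated aim of the series, is the interaction of all 3 factors. It called 0 IDs with limma, with a smallest adjusted p of 0.741 and 773 IDs at an unadjusted p under 0.05. Its median SE was 0.149 log2, against 0.0746 for KO minus WT in young cortex. Recovery was not simulated for any interaction, so 0 calls do not show that a difference is absent. The difference between regions in the effect of genotype called 0 IDs in young mice, with 545 at an unadjusted p under 0.05, and 0 in old mice, with 493. In young mice 4 were called without KO cortex replicate 1.

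The age change of WT mice differed between hippocampus and cortex in 292 IDs. In 213 the change was higher in hippocampus and in 79 it was lower. ENSMUSG00000064365 had a difference of 1.41 log2 (SE 0.37, adjusted p = 0.049) and ENSMUSG00000061897 of 1.37 (SE 0.27, adjusted p = 0.016), calls lost under 16 and 3 of the alternative settings. ENSMUSG00000010175 had a difference of -0.81 (SE 0.13, adjusted p = 9.6e-03) and ENSMUSG00000009075 of -0.78 (SE 0.13, adjusted p = 9.7e-03). Of the 213, 164 were called as rising in hippocampus and 7 as falling in cortex. Of the 79, 34 fell in hippocampus and 20 rose in cortex.

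The count of 292 was the least stable of these results. It ranged from 6, without old WT cortex replicate 3, to 597, without young WT cortex replicate 3. It was 58 and 180 without young WT cortex replicates 1 and 2, 69 and 524 without old WT cortex replicates 1 and 2, 171, 28 and 103 without young WT hippocampus replicates 1 to 3, 72, 103 and 135 without old WT hippocampus replicates 1 to 3, and 519 without young KO hippocampus replicate 1. After quantile normalization 261 were higher and 209 lower in hippocampus, and after median centring 182 and 240.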

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

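The tests of spread in each genotype, of swapped labels and of 1 array within a genotype were chosen after the results were seen. The planned test of 1 array, that of other splits, and those on the array that stood apart, were set down before their values were seen.

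A difference between regions, tested as an interaction, flagged 292 IDs whose WT age change differed between hippocampus and cortex, and the 4 IDs named for it. The differences, hippocampus minus cortex, were 1.41 log2 for ENSMUSG00000064365, 1.37 for ENSMUSG00000061897, -0.81 for ENSMUSG00000010175 and -0.78 for ENSMUSG00000009075. Of 100 draws that permuted age within each region of the WT arrays, the real one included, 3 called as many IDs and 84 called 0. This excludes chance at the 0.05 level only for age having no effect in either region. Mixing old and young arrays removes the age effect and widens the spread, so the draws do not test whether the regions differ. The highest other draw called 909, reached in 2 draws in which 0 of the 6 WT hippocampus arrays kept their age. In both of these draws 2 of the 6 WT cortex arrays kept theirs. The hippocampus age change entered them whole with its sign reversed, so age itself enters this count. Another draw with the same numbers kept called 0, and draws keeping 4 cortex and 0 hippocampus ages called 10. What set the count of 909 was not tested. In KO mice 202 of the 213 IDs with a higher change in hippocampus and 74 of the 79 with a lower one had the same sign, with a median difference of 0.188 against 0.456 log2 in WT, and of -0.258 against -0.414. The WT medians come from IDs picked for being large in WT and are inflated.

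More IDs were called with age in hippocampus (714 WT, 771 KO) than in cortex (148, 239). The fit gives each ID 1 spread, so the median SE was 0.0746 log2 in cortex and in hippocampus by construction. A greater spread between cortex arrays can therefore not lower the cortex count through the test, which is a property of the fit and not a result. In KO the median within-group SD of cortex over hippocampus was 0.775 and stayed between 0.717 and 0.972 without each array in turn. The SD was 0.103 in KO hippocampus and 0.0797 in KO cortex, so the shared SE can be too small for KO hippocampus. In WT the ratio was 1.21 (1.08 to 1.28). Fits to the arrays of 1 region, where WT calls were 117 in cortex and 396 in hippocampus, therefore leave a greater cortex spread open. The test planned for this, the ratio of WT age changes in hippocampus over cortex among IDs called in KO cortex, gave 0.528 (95% bootstrap interval over IDs 0.374 to 0.712). This met the planned criterion for the explanation, a ratio of 1 or less, and the criterion was set aside after its value was seen, because IDs chosen for changing in cortex favour cortex. IDs chosen in KO hippocampus had a median WT change of 0.221 log2 in hippocampus and 0.0026 in cortex. This choice favours hippocampus in the same way, so these medians do not decide the question either. In fits without 1 array, the hippocampus count stayed above the cortex count of the same genotype in each, but its excess over cortex narrowed to 177 against 131 in WT without young hippocampus replicate 2 and to 271 against 254, a ratio of 1.07, in KO without old hippocampus replicate 1, so how much of it rests on 1 array stays open, as does a biological difference between the regions, which the interaction tests only in WT. The planned test of 1 array set the lowest hippocampus count, 177, against the highest cortex count without 1 array of the compared groups, 312. It too met the criterion for the explanation, and was set aside after its value was seen because the 2 counts come from different genotypes.

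Replicate 1 of young KO hippocampus stood apart from its group. A trend with signal level is argued against, as a smooth curve on mean level explained 6.99% of the variance of its deviations. Cortex RNA in the pool is argued against too, as the deviations had a correlation of -0.025 (slope -0.014) with the cortex minus hippocampus difference of young WT mice. Contamination by other tissue and differences between the pooled mice stay open, because marker genes could not be matched to IDs, and no biological explanation was tested.

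KO and WT arrays were told apart by ENSMUSG00000022548. For this ID 12 of the 12 KO arrays lay below each WT array of their region and age. The ID was chosen for its separation, so that count decides nothing by itself. Chosen instead as the ID with the largest difference on the 6 arrays of 1 region and age, it was the same ID in each of the 4 cases, and 9 of the 9 other KO arrays lay below all other WT arrays, by at least 3.34 log2. A swap of some labels is argued against. An exchange of all KO and WT labels stays open, as the ID is not tied to the targeted gene here.

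For each comparison of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. In KO minus WT, 1 of the 10 splits called as many IDs in young cortex (real 1, highest other 0), 1 in old cortex (1 and 0), 2 in young hippocampus (1 and 1) and 1 in old hippocampus (1 and 0). In old minus young, it was 1 in WT cortex (148 and 2), 1 in KO cortex (239 and 0), 1 in WT hippocampus (714 and 0) and 1 in KO hippocampus (771 and 1). The other splits mix the 2 real groups, which removes a real effect and widens the spread of the IDs that changed. Their low counts are thus partly built in. For KO minus WT averaged over regions and ages, genotype was permuted within region and age in 100 draws, the real one included. Of these, 2 called as many as the real 2, and the highest other draw called 126, for a reason not tested. The share under 0.05 excludes chance only for genotype having no effect on any ID. Since ENSMUSG00000022548 is 1 of the 2 real calls, the share does not decide whether ENSMUSG00000038094 was called by chance. For the results with 0 calls each of the 100 draws calls at least as many by construction, so the draws decide nothing there. The highest other draw called 7 for age by genotype in cortex, 86 in hippocampus, 62 for the interaction of all 3 factors, and 1 for genotype by region in young mice and 1 in old mice. The reason for the draws with 86 and 62 calls was not tested either.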

How the results depend on the processing

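The leave-one-out values of the named IDs and of the age scores were added after the data were seen. Over the alternatives, 392 values of named IDs stayed called in the same direction, 48 were no longer called and 0 reversed. The fall of ENSMUSG00000022548 in KO stayed called in each. Of the counts, 245 stayed within 1.5 times the main count and 45 moved further. No scaling moved the median of all IDs by more than 0.037 log2 from 0 in any comparison, yet quantile normalization and median centring changed the balance of rising and falling age calls, as given with each count.

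With array weights, the count went from 1 to 2 for KO minus WT in young hippocampus and from 1 to 2 in old hippocampus, and the age calls went to 500 in KO cortex and 2219 in WT hippocampus. The age by region count of 292 went to 931 with array weights, 160 with no filter, 463 with the 60th percentile filter and 470 after quantile normalization. From hippocampus arrays alone, age calls were 396 in WT and 476 in KO, with fewer arrays to estimate the spread. At an adjusted p under 0.1, shared age calls were 631 for WT and KO in hippocampus, 65 for cortex and hippocampus in WT and 114 in KO. Why these counts moved was not tested.

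Without 1 array of the compared groups, counts for KO minus WT ran from 1 to 9 in young cortex, 1 to 2 in old cortex and 1 to 2 in old hippocampus. Age calls ran from 70 to 167 in WT cortex, 65 to 312 in KO cortex, 177 to 509 in WT hippocampus and 271 to 899 in KO hippocampus. Age by genotype in cortex ran from 0 to 2, genotype by region in young mice from 0 to 4, and age by region in WT from 6 to 597. The KO over WT ratio of age scores in cortex ran from 1.40 to 9.82. All arrays share the spread of each ID, so arrays outside the compared groups were also left out, a choice made after the data were seen. Without young KO hippocampus replicate 1, age calls were 364 in KO cortex, 207 in WT cortex and 1009 in WT hippocampus, age by region in WT gave 519 and age by genotype in cortex 3. Without young KO hippocampus replicate 3, KO minus WT in old cortex gave 2. No other such omission moved a count by over 1.5 times. A group left with 2 arrays shares the spread of the others.

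With the replicate number as a block, KO minus WT in young hippocampus called 2 IDs in place of 1, and no other count moved by over 1.5 times. No pairing by number was seen, since in no comparison did all 3 same-numbered pairs correlate above 0.1. The values were -0.214, -0.225 and -0.221 for KO minus WT in young hippocampus. Within regions, not every sample correlated best with its own number, and this was not computed across regions. Young KO cortex and hippocampus pairs had 0.049, 0.29 and 0.154, with a mean of -0.082 for other pairs. With 3 arrays a group, such values cannot show that the pools were unpaired. Same-numbered pools of both regions had a consensus correlation of 0.0067, and as a random block gave 306 age by region calls.

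Not run were the alternatives for Apod by name and for the gene lists, which need gene names, and those for linear values, as the values are log2. Without detection calls, how far dim IDs lie above background is unknown.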

Other observations

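The age scores were chosen after the calls had been seen. The tests of the 2 hypotheses were set down before the scores were computed, and the test of 1 array after.

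IDs called with age in both genotypes of one region were scored on the arrays of the other. For the 47 IDs from cortex, the score was the mean of 41 that rose minus the mean of 6 that fell. In hippocampus this score changed with age by 0.565 log2 in WT and 0.629 in KO. Each change had a two-sided exact permutation p of 0.1, the smallest that 3 arrays against 3 can give. The mean of the 41 IDs changed by 0.414 in WT and 0.423 in KO, and that of the 6 by -0.150 and -0.206. The score of the 317 IDs from hippocampus changed in cortex by 0.081 in WT (exact permutation p = 0.5) and 0.189 in KO (p = 0.1). The mean of the 263 that rose changed by 0.087 in WT and 0.171 in KO (exact permutation p = 0.1 each). The mean of the 54 that fell changed by 0.0057 in WT (exact permutation p = 0.9) and -0.017 in KO (p = 0.5). Of the 714 IDs called in WT hippocampus, 45.1% had the same sign in WT cortex, and of the 771 called in KO hippocampus 74.1% had the same sign in KO cortex. The difference between these shares was not tested.

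One hypothesis was that loss of ApoD brings the age change forward, so that young KO arrays would score above young WT arrays. The young KO mean minus the young WT mean was -0.035 log2 in hippocampus (exact permutation p = 0.9) and -0.019 in cortex (p = 0.9). Of the 3 young KO arrays, 1 in hippocampus and 0 in cortex lay above all young WT arrays. The planned criterion against the hypothesis was a young KO mean at or below the young WT mean in at least 1 region. Both regions met it. That criterion takes no account of spread, and the differences were within the spread of the arrays, so a small shift stays open.

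A second hypothesis was that loss of ApoD enlarges or shrinks the age change. The KO over WT ratio of score changes was 2.33 in cortex and 1.11 in hippocampus. The KO minus WT difference of the age changes was 0.108 log2 in cortex and 0.064 in hippocampus, with exact permutation p of 0.295 and 0.39 over 400 arrangements of genotype within age. The ratio in cortex ran from 1.40, without young WT replicate 1, to 9.82, without young WT replicate 3, because the WT change is near 0. These values do not decide whether 1 array or the genotype sets the ratio.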
